A study of Arabidopsis thaliana with 18 samples.

How the data were processed

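The series measured transcript levels in whole Arabidopsis thaliana seedlings on an Affymetrix oligonucleotide array of 22810 probe sets, 64 of them controls. Seedlings of 3 genotypes were 7 days old and grew at 22 °C on medium with MS salts at a strength of 0.5 and 1% sucrose. The genotypes were wild type of the accession Col-0 (WT), a line that overexpresses the heat shock factor HSFA6b (HSFA6b-OE, here OE), and a line that carries a dominant-negative form of it (HSFA6b-RD, here RD). Each genotype was left untreated, exposed to 37 °C for 1 h (heat shock), or exposed to 150 mM NaCl for 6 h. Each of the 9 groups held 2 biological replicates, 18 arrays in all, and 10 µg of RNA went into each labelling. Arrays are named here by genotype, treatment and replicate number, so that WT heat 1 is replicate 1 of the heat-shocked wild type.

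Per the labels, the authors ran MAS5, whose version is not given in the sources used here, to make an intensity (the signal) for each probe set. They also deposited the detection p-value and the call Present, Marginal or Absent made from it. The deposited intensity values are on a linear scale, and the mean after trimming 2% at each end lay between 500 and 500.1 on every array, so each array was scaled to a common mean before deposit. A value table of the whole series held the same signals, with a largest difference of 0. The highest deposited detection p of a Present call was 0.0474. No genome build is named with the values, so no coordinates are given.

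From these files, signals were taken to log2 with a floor of 0.1, which replaced 24 values of 0, of which 1 lay in a tested probe set. In all, 127 values of tested probe sets lay below 1, including that 0. Tested were the 17379 probe sets called Present on both arrays of at least 1 group, out of 22746 other than controls. The floor, the filter and the scaling can each change a number: fold changes of dim probe sets rest on values near background. Where a group had no Present array, a fold is therefore given as "at least", computed from mean log2 signals against the lowest signal called Present on each array where this exceeds the measured one, and left out where the ratio of the mean signals is smaller. No fold is given where both groups lacked a Present call.

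A table of the platform's annotation gave 1 gene symbol for 13513 probe sets, several for 503 and none for 8730. Through gene numbers, 13436 probe sets were matched to current symbols, and 63 more took a name that their description in the array files states. Of the tested probe sets, 9677 had exactly 1 gene assigned, 1355 of them with a name other than a locus code. Members known only by locus are printed by locus. No probe set was named for HSFA6B, so its level is not analysed here, and the planned check of the labels through it was not made.

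Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over all 18 arrays, with 9 residual and 4.76 prior degrees of freedom. The 16 contrasts were heat shock and NaCl against control in each genotype, OE and RD against WT in each treatment, and the difference of each response between OE or RD and WT. P values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Where nothing differs, a share of 0.05 of the 17379 tested probe sets is expected at an unadjusted p under 0.05. The counts for OE against WT under control and NaCl, and for RD against WT under control, lay below that share. So did those for the differences of the NaCl response, and none of these counts is a sign of further differences. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the figures. Changes are given as log2 differences with their standard error (SE), and levels as the mean signal with its standard deviation (SD) over 2 arrays. Arrays have no counting depth, so the precision depends on the number of arrays and, for dim probe sets, on background. Present calls per array ran from 14402 to 16739 (63.32% to 73.59%), the median signal from 147.2 to 206.7, and the lowest signal called Present from 6.2 to 14.6. The fit was also run on simulated data with the mean over all arrays and the residual spread of each of the 17379 probe sets. Known changes were set in WT heat alone. For heat shock against control in wild type it recovered 17 of 100 genes changed by a log2 fold of 1 and 66 of 100 changed by a log2 fold of 2. In that run 5 calls were false. Far fewer probe sets were changed there than passed for a treatment here, so these shares need not hold for the treatment contrasts.

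The design, 19 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation. This was possible for lists with at least 2 tested members. The lists covered heat shock factors, small heat shock proteins, HSP70, HSP90, HSP100 and co-chaperones, endoplasmic reticulum folding, genes responsive to ABA (abscisic acid) and osmotic stress, ABA synthesis, breakdown and signalling, DREB and CBF factors, sodium transport and the SOS pathway, and antioxidant enzymes with zinc finger stress factors. They also covered photosynthesis, cytosolic ribosomal proteins, jasmonate, salicylate and defence, flavonoid synthesis, auxin response, cell division, root markers, seed storage and late embryo, and reference genes. Members were matched by gene name and needed a detected probe set assigned to their gene, which left 5 of the 18 small heat shock proteins. Other lists shrank too, to 3 of 20 heat shock factors, 2 of 22 jasmonate genes and 5 of 11 flavonoid genes. Of ABA synthesis and signalling 4 of 38 genes were tested, and of photosynthesis 4 of 23. A list result stands for its tested members alone. A version of the small heat shock protein list matched by locus alone (14 tested), 2 lists of the probe sets of the plastid and mitochondrial genomes, and 18 lists drawn from the descriptions in the array files were added after the data were seen. Of the latter, the list of auxin-related descriptions was written after fold changes were known. The plastid list took probe sets by chromosome. The mitochondrial list took only probe sets without a locus whose symbol begins with matR, orfX, or nad, ccb or cox and a digit. Mitochondrial genes of other names are not in it. A list fixed in advance also has its members' calls adjusted over the list alone.

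For each contrast, the rule named the 8 largest rises and the 8 largest falls past the threshold among probe sets of exactly 1 named gene whose arrays did not overlap between the groups (4 each way for a difference of responses). It added up to 4 members of each fixed list, by adjusted p, and allowed any member of the heat shock factor, DREB and small heat shock protein lists. The probe set with the highest mean signal stood for a gene. Other genes are marked in the text as chosen after their values were seen.

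The alternatives were quantile normalization, no detection filter, log2 of the signal plus 32, the replicate number as a block, eBayes without the intensity trend, only the groups compared in the fit, and the series value table. Arrays fall into 2 series by their array names, and 3 of the 18 (WT heat 1, WT NaCl 1 and OE NaCl 1) belong to the second. The series was therefore tried as a block, and the 3 arrays were left out. The labels do not say what a replicate number marks. Replicate differences of the 3 genotypes correlated at 0.3 to 0.4 under control and 0.291 to 0.627 under NaCl, where WT and OE also share the array series by number, but at -0.055 to 0.122 under heat shock. After the other alternatives had been run, the numbers were therefore taken to pair arrays within control and NaCl, and a fit with the replicate number as a block within these 2 treatments was added for the genotype comparisons. Every array was also left out in turn, in which case the remaining array of its group is assumed to vary like the other groups. The OE and RD contrasts share the WT arrays, and the heat shock and NaCl contrasts share the control arrays, so correlations and overlaps stand beside values for unchanged groups. These came from each group's own replicate differences for the correlations, and from 20 simulations for the overlap. Scanner images were not used here.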

Results

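Transcript levels were measured in whole seedlings of 3 genotypes under 3 treatments, with 2 arrays in each of the 9 groups. Between 63.32% and 73.59% of the probe sets were called Present on an array. The first principal component of the log2 signals held 41.9% of the variance and set the 6 NaCl arrays (67.6 to 120.71) apart from all others (-60.77 to -33.35). The second held 27.4% and parted the 6 heat shock arrays (-81.15 to -57.1) from the 6 control arrays (62.96 to 74.47). Across genes, which are not independent replicates, the arrays of a group correlated at 0.916 to 0.973. The 3 lowest of the 9 values, 0.916 for WT NaCl, 0.917 for WT heat and 0.935 for OE NaCl, belonged to the groups with 1 array of the second series. Replicate differences had an SD across genes of 0.904 in WT heat and in WT NaCl, and of 0.5 to 0.77 in the other groups. The SE pools the spread of all groups, so it can understate that of WT heat and WT NaCl.

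**Figure D1:**
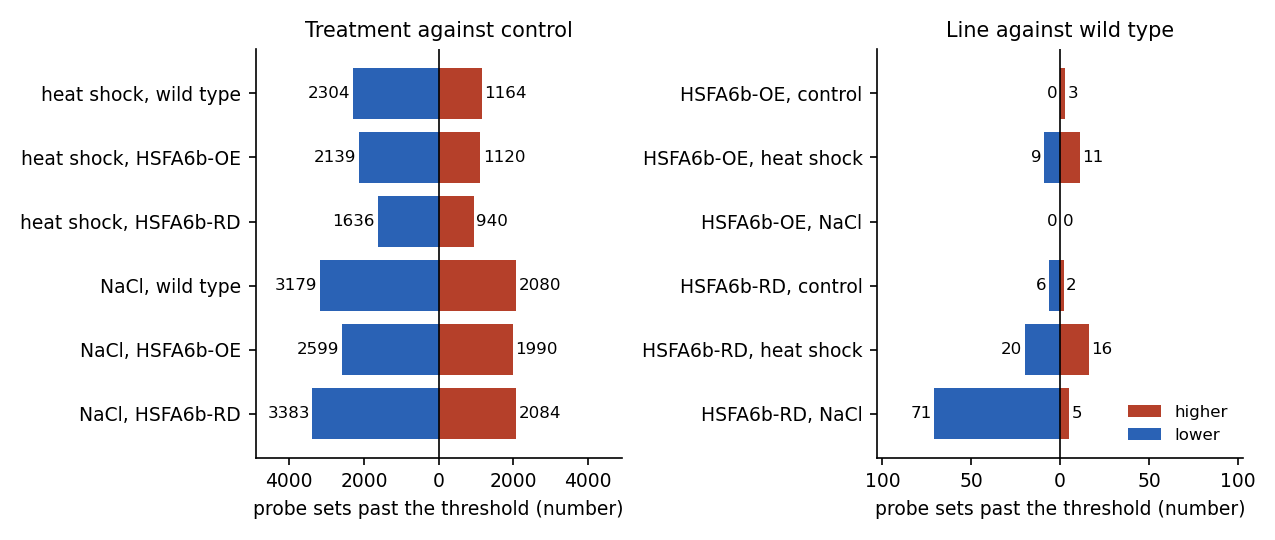
The bars give the number of probe sets past the threshold, higher to the right and lower to the left, for each treatment against control (left) and for each line against wild type (right, on its own scale). Between 2576 and 5467 probe sets passed for a treatment, whereas 0 to 76 differed between a line and wild type.

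Heat shock against control in wild type shows which transcripts had changed after 1 h at 37 °C. The largest rises belonged to heat shock proteins, chaperones that hold or refold unfolded proteins. HSP101, a protein disaggregase, rose from a mean signal of 46.7 ± 21.6 (SD, n = 2) to 40600 ± 3590, by a log2 difference of 9.84 ± 0.50 (SE, adjusted p = 9.59e-09), from a level not called Present. HSP90.1 rose from 222.8 ± 13.8 to 39310 ± 200, by 7.46 ± 0.26 (adjusted p = 2.38e-10). The other 6 of the 8 largest rises were those of plastid HSP21 (10.42 ± 1.28), mitochondrial HSP23.6-MITO (10.00 ± 0.65), the small heat shock proteins HSP17.6A (8.81 ± 0.45), ATHSP22.0 (8.63 ± 0.60) and HSP17.6II (8.48 ± 0.51), and the HSP70 co-chaperone Fes1A (7.57 ± 0.27). Among the largest falls were TRM24 (-5.67 ± 0.56, at least 8.80-fold), AGO7, which acts in the trans-acting small RNA pathway (-4.48 ± 0.73, at least 7.92-fold), the tetraspanin TET6 (-4.01 ± 0.46, at least 13.71-fold), the beta-glucosidase BGLU33 (-3.58 ± 0.45) and the root patterning factor SCR (-3.31 ± 0.58). TRM24, AGO7 and TET6 were not called Present after heat shock, nor HSP23.6-MITO under control, so their log2 differences and ranks rest on values near background.

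In all, 3468 of 17379 probe sets passed the threshold in wild type after heat shock, 1164 higher and 2304 lower. The median over all probe sets lay at -0.29, and at -0.13 after quantile normalization, which moved the share of rises among the calls from 33.6% to 49.5%. Fewer probe sets passed without WT control 1 (1877) or WT control 2 (1682), and 5220 with the array series as a block. All 5 small heat shock proteins of the list rose, also when adjusted over the list alone, as did 12 of 13 HSP70, HSP90, HSP100 and co-chaperone genes, among them HSP70 (6.43 ± 0.32), Hop3 (7.43 ± 0.39) and Hsp70-2 (4.89 ± 0.48). Hop1 had a value of -0.39 ± 0.30. The upward shifts of both lists passed camera (adjusted p = 5.64e-13 and 5.24e-27) and also had adjusted p = 0.0315 and 0.00621 with an estimated correlation. Matched by locus alone, 12 of 14 small heat shock proteins rose, with a median of 8.39 (adjusted p = 5.11e-26, and adjusted p = 0.00999 with an estimated correlation). AT4G21870 and AT5G47600 stood at -0.05 and -0.76. Of the heat shock factors, HSF4 rose by 6.32 ± 0.29, while HSF1 (-0.48 ± 0.38) and HSF3 (0.00 ± 0.28) did not pass, nor did the list of 3 (adjusted p = 0.0635). A list of 24 probe sets described as heat shock factors, added after the data were seen, shifted up with 12 higher and 0 lower (adjusted p = 1.44e-11, and adjusted p = 0.000308 with an estimated correlation).

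Stress factors outside the chaperones also rose with heat shock in wild type. The drought and heat factor DREB2A rose by 6.08 ± 0.28 and DREB2B by 3.44 ± 0.56, whereas the cold factors CBF1 (1.71 ± 0.77) and CBF2 (0.12 ± 0.57) did not pass. The list of 4 shifted up with adjusted p = 0.000291, and had adjusted p = 0.0641 with an estimated correlation. All 3 genes of the antioxidant and zinc finger list rose, RHL41 by 5.06 ± 0.53, STZ by 4.31 ± 0.31 and GSTF8 by 3.02 ± 0.26 (adjusted p = 2.48e-07, and adjusted p = 0.0151 with an estimated correlation). The dehydrins COR47 (2.85 ± 0.35) and LTI30 (2.71 ± 0.36) and the desiccation gene LTI78 (649.1 ± 2.33 to 1844 ± 211, 2.83-fold) rose among 11 genes responsive to ABA and osmotic stress, 3 also when adjusted over the list alone. That list shifted up with adjusted p = 0.00445, but had adjusted p = 0.417 with an estimated correlation. LTI78 no longer passed without any 1 of the 4 arrays, with a highest adjusted p of 0.126. The membrane-bound factor BZIP28 alone rose among 5 endoplasmic reticulum folding genes (2.44 ± 0.19). Their shift up had adjusted p = 0.0375, adjusted p = 0.108 with an estimated correlation, adjusted p = 0.105 after quantile normalization, and up to 0.0832 without WT control 1, WT heat 1 or WT heat 2.

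The remaining fixed lists showed few or no calls with heat shock in wild type, and none of them passed camera. SCR and SHR, which pattern the root, fell among 6 root markers (adjusted over the list alone, also 2; adjusted p = 0.608). SHR (-2.32 ± 0.74) lost its call without any 1 of the 4 arrays, with a highest adjusted p of 0.179. In the lists of salicylate and defence and of jasmonate, PR5 rose (1.59 ± 0.41), while EDS1 (-1.13 ± 0.34) and the jasmonate synthesis gene LOX2 (-1.66 ± 0.43) fell. Of these, PR5 (0.0877) and EDS1 (0.273) missed the threshold without WT control 1, WT control 2 or WT heat 2, and LOX2 (0.183) without WT heat 1 or WT control 2. Lists had adjusted p = 0.677 for salicylate and defence, where the median was -0.10 and the mean 0.07, and adjusted p = 0.39 for jasmonate. No member passed for ABA synthesis and signalling (4 tested, adjusted p = 0.677, with a median of 0.25 and a mean of -0.01), flavonoid synthesis (5 tested, adjusted p = 0.608), photosynthesis (4 tested, adjusted p = 0.608) or seed storage (2 tested, adjusted p = 0.281). The median of the 4 photosynthesis genes was 0.01 as deposited and -0.59 after quantile normalization. Among 7 auxin response genes the conjugating enzyme WES1 fell (-1.31 ± 0.44), with 0 when adjusted over the list alone and a highest adjusted p of 0.243 without WT control 1, WT control 2 or WT heat 2. The auxin list had a median of -0.14, a mean of -0.41 and a camera direction of up (adjusted p = 0.979). The polyubiquitin gene UBQ10 rose among 4 reference genes (0.75 ± 0.24; list adjusted p = 0.161), but stood at 0.03 after quantile normalization, and without WT control 1, WT control 2 or WT heat 2 its adjusted p reached 0.229. The single tested members of 3 lists did not pass, SOS2 for sodium transport (-0.17 ± 0.44), PGY1 for cytosolic ribosomal proteins (-0.43 ± 0.32) and CYCB1;1 for cell division (-1.08 ± 0.60).

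In OE, the same comparison asked how the overexpressing line responded to heat. HSP101 (9.39 ± 0.50), HSP23.6-MITO (8.51 ± 0.65), Fes1A (7.06 ± 0.27), HSP90.1 (7.06 ± 0.26), the co-chaperone Hop3 (7.00 ± 0.39) and HSP17.6A (6.84 ± 0.45) were among the largest rises. HSP101 and HSP23.6-MITO were not called Present in the OE controls, so their differences and ranks rest on values near background. All 5 small heat shock proteins rose (adjusted p = 9.83e-11, and adjusted p = 0.0405 with an estimated correlation), although HSP21 (5.63 ± 1.28) had adjusted p = 0.0714 without OE control 1 or OE heat 1. So did 12 of 13 HSP70, HSP90, HSP100 and co-chaperone genes (adjusted p = 5.29e-28, and adjusted p = 0.00545 with an estimated correlation). HSF4 rose by 5.55 ± 0.29, DREB2A by 4.78 ± 0.28, BZIP28 by 2.61 ± 0.19 and the endoplasmic reticulum co-chaperone ATERDJ3B by 1.57 ± 0.29. Falls included the expansins EXPA8 (-3.02 ± 0.61) and EXPA15 (-2.90 ± 0.46), which loosen cell walls, P1R1 (-3.11 ± 0.34), and the auxin-responsive repressor IAA29 (-4.45 ± 0.82, at least 21.87-fold). With 4 of 7 members lower, both over all probe sets and adjusted over the list alone, the auxin list shifted down (adjusted p = 0.0275), but had adjusted p = 0.417 with an estimated correlation and 0.166 without OE control 1. Of 3259 calls, 1120 were higher and 2139 lower, at a median of -0.29, or -0.13 and 51.6% rises in place of 34.4% after quantile normalization. The count was 1402 without OE control 1, 1587 without OE heat 1, 1547 without OE control 2 and 1932 without OE heat 2, and 4921 within the first array series.

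RD carries the dominant-negative form, and the same comparison asked which heat-responsive transcripts still changed in it. Among named genes, HSP23.6-MITO (11.91 ± 0.65, at least 2367-fold), HSP101 (10.87 ± 0.50), HSP21 (10.37 ± 1.28), HSP17.6A (9.98 ± 0.45) and HSP17.6II (8.82 ± 0.51) rose with heat shock. HSP23.6-MITO and HSP101 were not called Present in the RD controls, so their differences rest on values near background. All 5 small heat shock proteins rose (adjusted p = 4.69e-15, and adjusted p = 0.0151 with an estimated correlation), as did 12 of 13 HSP70, HSP90, HSP100 and co-chaperone genes (adjusted p = 4.17e-31, and adjusted p = 0.0037 with an estimated correlation). HSF4 rose by 6.79 ± 0.29, DREB2A by 5.88 ± 0.28 and BZIP28 by 2.42 ± 0.19. LTI30 (3.04 ± 0.36), LTI78 (2.56 ± 0.45), COR47 (2.34 ± 0.35) and LTI65 (2.08 ± 0.61) rose among 11 genes responsive to ABA and osmotic stress, 4 also when adjusted over the list alone. That list's median was -0.09, or 0.24 after quantile normalization, its mean 0.76, and camera gave an upward shift (adjusted p = 0.00405; adjusted p = 0.476 with an estimated correlation). Without any 1 of the 4 arrays LTI65 did not pass, with a highest adjusted p of 0.175. ATL8, a ubiquitin ligase of the ATL family (-3.40 ± 0.58), BGLU33 (-2.75 ± 0.45) and BRH1 (-2.64 ± 0.36) were among the largest falls. There were 2576 calls, 940 higher and 1636 lower, at a median of -0.27, or -0.10 and 55.1% rises in place of 36.5% after quantile normalization. The count was 1187 without RD control 1, 1074 without RD heat 1, 1444 without RD control 2 and 1381 without RD heat 2, and 4232 within the first array series.

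Transcripts of the mitochondrial genome list, which was picked by gene name, rose with heat shock in every genotype. Of 21 probe sets, 16 passed in wild type (median 3.57), 17 in OE (median 3.32) and 18 in RD (median 3.23), all upward. Camera gave adjusted p = 1.6e-20, 2.13e-21 and 5.77e-22, and adjusted p = 0.0649, 0.0689 and 0.0538 with an estimated correlation. Median log2 signals of these probe sets ran from 6.49 to 7.06 on control arrays and from 9.75 to 10.35 on heat shock arrays. Plastid genome transcripts did not move with them in wild type, where 0 of 69 probe sets rose and 4 fell (adjusted p = 0.135), with a median of 0.12, or -0.06 after quantile normalization, and a mean of -0.05. In OE the plastid list had 0 higher and 1 lower (adjusted p = 0.314). In RD, with 0 higher, 1 lower and a median of 0.235, it shifted up (adjusted p = 0.00156, but adjusted p = 0.647 with an estimated correlation, 0.109 after quantile normalization, and 0.275 without RD control 2, where its direction turned). Both lists were added after the data were seen.

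**Figure D2:**
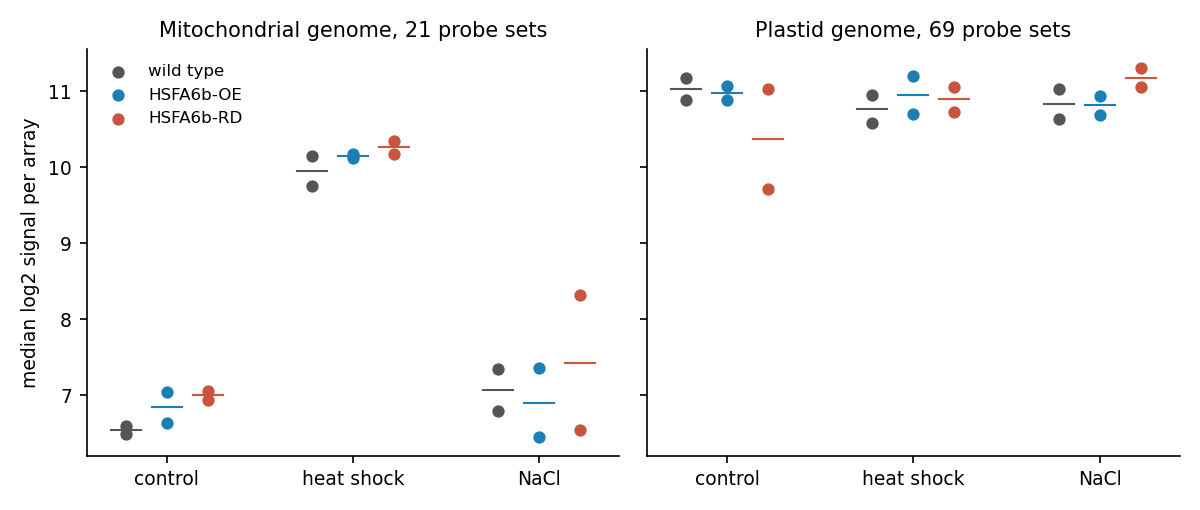
Each point is the median log2 signal of 1 array over the probe sets of the mitochondrial genome list, picked by gene name (left), or of the plastid genome (right), by treatment and genotype. Each short line is the mean of 2 arrays. Mitochondrial medians lie between 9.75 and 10.35 on all 6 heat shock arrays; RD NaCl 1 (8.32) and, for the plastid, RD control 2 (9.72) stand apart from the other arrays of their treatments.

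NaCl against control in wild type shows the transcripts that had changed after 6 h in 150 mM NaCl. Heat shock proteins were again among the largest rises, led by HSP101, from 46.7 ± 21.6 to 16480 ± 629 (8.54 ± 0.50, adjusted p = 1.16e-07). HSP17.6A (7.73 ± 0.45), HSP23.6-MITO (7.07 ± 0.65), Fes1A (6.78 ± 0.27) and HSP90.1 (5.63 ± 0.26) followed. DREB2A rose from 176.9 ± 34.5 to 15270 ± 3650, by 6.42 ± 0.28 (adjusted p = 8.64e-09), and the glutaredoxin GRX480 from 38.55 ± 12.8 to 3184 ± 207, by 6.41 ± 0.34 (adjusted p = 5.24e-08). The largest falls included cell wall loosening expansins, EXPA4 (-3.96 ± 0.57) and the root hair gene EXPA7 (-3.65 ± 0.68), together with DRT100 (-3.64 ± 0.38) and TRM22 (-3.72 ± 0.62). PDF2.5 (-4.49 ± 1.11) and the glutathione transferase GSTU20 (-3.97 ± 1.04) also fell, but reached adjusted p = 0.112 and 0.162 without WT control 2 or WT NaCl 2. EXPA7, TRM22 and PDF2.5 under NaCl and HSP101 and HSP23.6-MITO under control were not called Present, so their exact differences rest on values near background.

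With NaCl, 5259 probe sets passed in wild type, 2080 higher and 3179 lower, at a median of -0.19, or -0.08 after quantile normalization. The count was 3289 without WT control 1, 2648 without WT control 2 and 2537 without WT NaCl 2. Of 13 HSP70, HSP90, HSP100 and co-chaperone genes 11 rose, and 12 when adjusted over the list alone, with a shift up (adjusted p = 1.37e-13, and adjusted p = 0.0407 with an estimated correlation). HSC70-1 (0.53 ± 0.23) and Hop1 (-0.25 ± 0.30) did not pass. Of 5 small heat shock proteins 4 rose, and 5 when adjusted over the list alone (adjusted p = 9.52e-06, but adjusted p = 0.145 with an estimated correlation). HSP21, at 239.4 ± 14.6 against 43.35 ± 53.5, did not pass, and ATHSP22.0 (1.87 ± 0.60) reached adjusted p = 0.268 without WT control 1 or WT NaCl 1. By locus alone 11 of 14 rose (median 4.26, adjusted p = 1.6e-11, and adjusted p = 0.0484 with an estimated correlation). HSF4 rose by 2.47 ± 0.29, while HSF1 (0.72 ± 0.38) and HSF3 (0.61 ± 0.28) did not pass. The list of 3 shifted up with adjusted p = 0.0261, and had adjusted p = 0.124 with an estimated correlation.

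Osmotic stress, ABA and auxin lists differed in how many members rose under NaCl in wild type. All 4 DREB and CBF factors rose, with DREB2B at 4.39 ± 0.56, CBF1, not called Present in either group, at 3.71 ± 0.77 and CBF2 at 2.73 ± 0.57 (adjusted p = 2.4e-05, and adjusted p = 0.0407 with an estimated correlation). CBF2 had adjusted p = 0.0506 without WT NaCl 2. STZ (4.81 ± 0.31), RHL41 (4.77 ± 0.53) and GSTF8 (2.12 ± 0.26) rose (adjusted p = 2.9e-05, and adjusted p = 0.0407 with an estimated correlation). Among 11 genes responsive to ABA and osmotic stress, 5 rose, and 6 when adjusted over the list alone, including LTI78 (2.58 ± 0.45), COR47 (2.33 ± 0.35) and LTI30 (1.99 ± 0.36). COR15A (4.25 ± 1.04) reached adjusted p = 0.115 without WT control 2 or WT NaCl 2. This list shifted up (adjusted p = 0.000209), but had adjusted p = 0.333 with an estimated correlation. The ABA co-receptor phosphatase ABI1 rose (2.85 ± 0.42), as 1 of 4 genes of ABA synthesis and signalling, and 2 when adjusted over the list alone (adjusted p = 0.125). In the auxin list 4 of 7 rose, 6 when adjusted over the list alone, among them the conjugating enzyme GH3.3 (5.05 ± 0.53) and the repressor IAA2 (1.78 ± 0.35). Its shift had adjusted p = 0.000663, and adjusted p = 0.304 with an estimated correlation.

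Of 6 root markers 4 fell, and 5 when adjusted over the list alone, among them EXPA18 (-2.27 ± 0.41) and SHR (-3.48 ± 0.74). SHR had adjusted p = 0.0515 without WT NaCl 2. The list shifted down (adjusted p = 0.0266), with adjusted p = 0.349 with an estimated correlation and 0.0732 without WT NaCl 2. The mitotic cyclin CYCB1;1 fell by 2.53 on the log2 scale (SE 0.60), but had adjusted p = 0.0919 without WT control 2 or WT NaCl 2. The endoplasmic reticulum list was split, with BZIP28 higher (1.60 ± 0.19) and the calreticulin CRT1a lower (-1.46 ± 0.37), the latter at 0.119 without WT control 2 or WT NaCl 2. Its median was -0.71, its mean -0.11 and its camera direction up (adjusted p = 0.906). The flavonol synthase FLS1 fell (-2.30 ± 0.42; list adjusted p = 0.26). EXPA18, SHR, CYCB1;1 and FLS1 were not called Present under NaCl.

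In OE, NaCl raised HSP101 (8.14 ± 0.50), Fes1A (6.32 ± 0.27), GRX480 (6.21 ± 0.34), DREB2A (6.19 ± 0.28), HSP23.6-MITO (6.05 ± 0.65) and GH3.3 (5.93 ± 0.53). It lowered scpl40 (-4.85 ± 0.87, at least 6.71-fold), the wall enzyme XTH26 (-4.35 ± 0.70, at least 10.69-fold), EXPA4 (-3.94 ± 0.57) and DRT100 (-3.73 ± 0.38). Of these, HSP101 and HSP23.6-MITO under control and scpl40 and XTH26 under NaCl were not called Present. Of 13 HSP70, HSP90, HSP100 and co-chaperone genes 11 rose (adjusted p = 3.13e-13, and adjusted p = 0.0307 with an estimated correlation), as did all 4 DREB and CBF factors (adjusted p = 9.75e-06, and adjusted p = 0.0307 with an estimated correlation). Among small heat shock proteins 3 of 5 rose (adjusted p = 0.00022, and adjusted p = 0.246 with an estimated correlation), while HSP21 (0.31 ± 1.28) and ATHSP22.0 (0.99 ± 0.60) did not pass. Auxin response genes rose in 6 of 7 cases, also when adjusted over the list alone (adjusted p = 4.07e-05, and adjusted p = 0.205 with an estimated correlation). The 4589 calls were 1990 rises and 2599 falls, at a median of -0.13. There were 2469 without OE control 1, 2215 without OE control 2 and 2076 without OE NaCl 2.

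In RD, NaCl raised HSP101 (8.97 ± 0.50), the glycosyltransferase UGT76E12 (7.89 ± 1.22), HSP17.6A (7.49 ± 0.45), DREB2A (6.46 ± 0.28), GH3.3 (5.99 ± 0.53) and the chloroplast protein COR15A (5.94 ± 1.04). Its largest falls included BZIP34 (-4.85 ± 0.40, at least 13.56-fold), the calmodulin-binding IQD19 (-4.82 ± 0.30, at least 15.43-fold), SHR (-4.69 ± 0.74, at least 14.02-fold) and CYCB1;1 (-4.41 ± 0.60, at least 9.723-fold). HSP101 and UGT76E12 were not called Present in the RD controls. Genes responsive to ABA and osmotic stress rose in 6 of 11 cases, 8 when adjusted over the list alone, with LTI78 at 4.89 ± 0.45 and LTI30 at 3.20 ± 0.36 (adjusted p = 3.11e-06, and adjusted p = 0.236 with an estimated correlation). Of 13 HSP70, HSP90, HSP100 and co-chaperone genes 11 rose (adjusted p = 1.34e-10, and adjusted p = 0.0508 with an estimated correlation). Among 5 small heat shock proteins 3 rose (adjusted p = 0.00189, and adjusted p = 0.308 with an estimated correlation), while HSP21 (0.60 ± 1.28) and ATHSP22.0 (-0.46 ± 0.60) did not pass. The auxin-responsive repressor IAA1 fell (-2.14 ± 0.32). Of 5467 calls, 2084 were higher and 3383 lower, at a median of -0.22, or -0.10 after quantile normalization. There were 3134 without RD control 2 and 3185 without RD NaCl 2, and on RD control 2 the plastid transcripts stood apart (median 9.72).

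The heat shock and NaCl responses of wild type overlapped. Both treatments raised 519 probe sets, where independent lists of the same sizes would share 139.3, and lowered 956, where they would share 421.5. Rises with heat shock and falls with NaCl met in 42 probe sets (212.9 for independent lists), and the opposite in 73 (275.8). Both comparisons use the WT control arrays, and part of the excess may come from the shared controls. In 20 simulations of unchanged groups no probe set passed in both with limma (highest 0), and 199 on average passed in the same direction at an unadjusted p under 0.05, against 2718 here. Unchanged groups give few calls, so these simulations cannot tell how much of the overlap among responding probe sets comes from the shared controls. The shared falls numbered 420 without WT control 1, 269 without WT control 2 and 588 without WT NaCl 2, and the shared rises 342 without WT control 2. Across genes the log2 differences correlated at 0.481. Unchanged groups gave 0.5 through the shared controls alone. That value holds where nothing responds, so it cannot tell whether the 2 responses are alike.

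OE against WT under control conditions asked what the overexpression changed in untreated seedlings. Only 3 probe sets passed, all higher, and they were chosen for naming after their values were seen. The first, described in the array files as a putative heat shock protein similar to heat shock transcription factors and not assigned to a gene here, stood at 1550 ± 144 in OE and 25.15 ± 3.75 in WT (5.95 ± 0.49, 61.9-fold, adjusted p = 0.000152). Whether it measures HSFA6B itself, the gene altered in both lines, is not given in the sources used here. The second, described as heat shock protein 18, stood at 1033 ± 96 and 146.2 (2.82 ± 0.26, 7.08-fold, adjusted p = 0.000307). It is 1 of the 19 tested probe sets described as small heat shock proteins, and was not matched to the fixed list. Under NaCl this probe set was lower in RD than in WT, at 176.7 ± 34.3 against 678 ± 7.85 (-1.95 ± 0.26, adjusted p = 0.00409 with limma). AT2G32140, described as a putative disease resistance protein, stood at 17 ± 3.82 in OE and at 1.05, where it was not called Present, in WT (adjusted p = 0.00195), and had adjusted p = 0.0687 without OE control 2. No small heat shock protein of the fixed list passed on its own, but 4 of 5 did when adjusted over the list alone, and the list shifted up with a median of 1.78 (adjusted p = 2.05e-20, and adjusted p = 0.0215 with an estimated correlation). HSP21 had a value of 4.85 ± 1.28, ATHSP22.0 of 2.92 ± 0.60, HSP17.6II of 1.78 ± 0.51, HSP17.6A of 1.73 ± 0.45 and HSP23.6-MITO of 1.29 ± 0.65. By locus alone the 14 members had a median of 1.29 (adjusted p = 3.34e-23, and adjusted p = 0.0299 with an estimated correlation). The HSP70, HSP90, HSP100 and co-chaperone list had a median of 0.17 (adjusted p = 0.026, but adjusted p = 0.71 with an estimated correlation, and 0.671 without WT control 1 or OE control 2). At an unadjusted p under 0.05 there were 159 probe sets, fewer than the share of 0.05 expected where nothing differs.

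Under heat shock, 20 probe sets differed between OE and WT, 11 higher and 9 lower (66.7% in place of 55% higher after quantile normalization). JMT, a jasmonate methyltransferase, stood at 74.5 ± 12.7 in OE and 4.45 ± 2.33 in WT (4.16 ± 0.49, at least 8.41-fold, adjusted p = 0.00523). TET6 was higher (2.92 ± 0.46, at least 6.43-fold, adjusted p = 0.0311), and TRM24, not called Present in either group, had a difference of 3.69 ± 0.56 (adjusted p = 0.0256). CCL was lower, at 1345 ± 71.5 against 14020 ± 10600 (-3.14 ± 0.45, 8.8-fold, adjusted p = 0.0221). JMT (0.067) lost its call without OE heat 1, CCL (0.109) without OE heat 1 or OE heat 2, and TRM24 (0.109) and TET6 (0.138) without WT heat 1, OE heat 1 or OE heat 2. No gene of the chaperone lists passed, with medians of -0.24 for small heat shock proteins and -0.16 for HSP70, HSP90, HSP100 and co-chaperones (0.07 after quantile normalization). Whether differences between genotypes still show at the high signals of these genes under heat shock was not tested. Auxin response genes shifted down, with 0 of 7 past the threshold and 3 when adjusted over the list alone (median -1.15, adjusted p = 2.56e-05, but adjusted p = 0.38 with an estimated correlation). The 2 tested jasmonate genes, LOX2 and AOS (median 1.70, adjusted p = 0.00292), and the 5 tested flavonoid genes (median 1.24, adjusted p = 0.0107) shifted up, with 2 in each list when adjusted over the list alone. These had adjusted p = 0.326 and 0.539 with an estimated correlation, and 0.0993 and 0.507 without WT heat 1. The count of 20 depended on single arrays, with 53 without WT heat 1, 662 without WT heat 2 and 1 without OE heat 1, 112 with the array series as a block or 119 within its first series, and 432 with the replicate number as a block within control and NaCl. At an unadjusted p under 0.05 there were 2350. In a fit of only the groups compared, 0 passed with limma.

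Under NaCl, 0 probe sets differed between OE and WT with limma. An unadjusted p under 0.05 was reached by 296, fewer than the share of 0.05 expected where nothing differs. The probe set described as a putative heat shock protein had a value of 3.61 ± 0.49 (adjusted p = 0.0627), after 817.8 ± 691 in WT. None of the 16 fixed lists passed camera, and small heat shock proteins had a median of 0.63 (adjusted p = 0.129, or 0.0044 with the replicate number as a block within control and NaCl, where it had adjusted p = 0.78 with an estimated correlation). Matched by locus, they had a median of 0.32 (adjusted p = 0.0182, but adjusted p = 0.824 with an estimated correlation and 0.445 without WT NaCl 1 or OE NaCl 2). There were 14 calls without WT NaCl 1, 1 without OE NaCl 1 and 2 without WT NaCl 2, 6 within the first array series and 1 with that block.

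RD against WT under control conditions asked what the dominant-negative form changed in untreated seedlings. LCR68, a small secreted protein of the defensin family, was lower, at 160.5 ± 51.9 against 3078 ± 415 (-4.29 ± 0.44, 19.6-fold, adjusted p = 0.000776). The probe set described as a putative heat shock protein was higher, at 3784 ± 476 against 25.15 ± 3.75 (7.24 ± 0.49, 151-fold, adjusted p = 1.23e-05). LCR68 was also lower in RD under heat shock (-3.28 ± 0.44) and NaCl (-3.49 ± 0.44), whereas in OE its differences of 0.35, 1.06 and 0.65 did not pass. In all 8 probe sets passed, 2 higher and 6 lower, 642 had an unadjusted p under 0.05, 15 passed with the array series as a block or 26 within its first series, and 32 with the replicate number as a block within control and NaCl. Small heat shock proteins shifted down (median -0.59, 0 past the threshold, 2 when adjusted over the list alone), as did HSP70, HSP90, HSP100 and co-chaperones (median -0.13, 0 and 2), each with adjusted p = 0.0149 and adjusted p = 0.598 with an estimated correlation. Without RD control 1 or WT control 2 these reached adjusted p = 0.794 and 0.451. Plastid transcripts had a median difference of -0.31 (adjusted p = 0.000771, but adjusted p = 0.725 with an estimated correlation). Their direction turned without RD control 2, on which plastid transcripts stood apart (median 9.72).

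**Figure D3:**
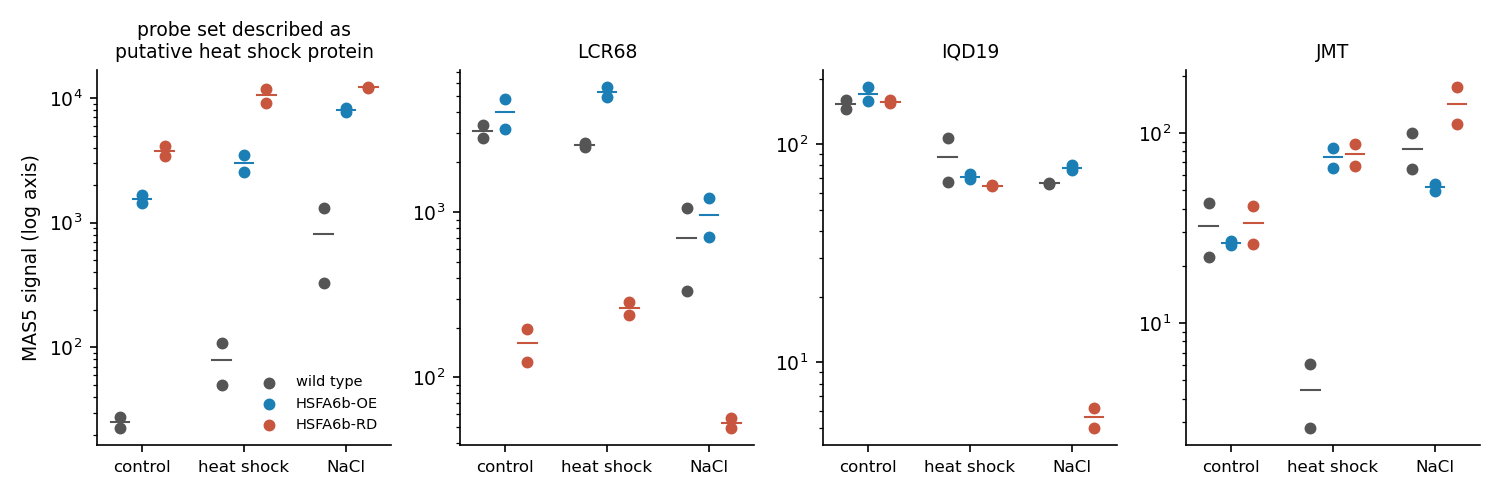
Each point is the MAS5 signal of 1 array on a log axis, by treatment and genotype, for 4 probe sets, and each short line is the mean of 2 arrays. The probe set described as a putative heat shock protein is higher in both lines than in wild type, with OE under NaCl not past the threshold; LCR68 is lower in RD under every treatment, IQD19 in RD under NaCl (5.6 against 66.25), and JMT lies lowest in wild type under heat shock (4.45).

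Under heat shock, 36 probe sets differed between RD and WT, 16 higher and 20 lower. JMT (4.21 ± 0.49, at least 8.70-fold, adjusted p = 0.00209) was higher, at 77.2 ± 14.3. LOX2, which starts jasmonate synthesis, stood at 3056 ± 2.12 against 582.1 ± 277 (2.48 ± 0.43, 5.57-fold, adjusted p = 0.0339), and the wall enzyme XTH18 at 2329 ± 460 against 679.9 ± 103 (1.77 ± 0.25, 3.41-fold, adjusted p = 0.00905). TRM24, not called Present in either group, had a difference of 3.73 ± 0.56 (adjusted p = 0.0114), and LCR68 was lower (9.74-fold, adjusted p = 0.006). Without single arrays the highest adjusted p was 0.231 for LOX2 (WT heat 1, RD heat 1 or RD heat 2; 0.0644 after quantile normalization), 0.15 for XTH18 (RD heat 1), 0.171 for TRM24 and 0.0592 for LCR68 (each RD heat 1 or RD heat 2). No gene of the chaperone lists passed, with medians of -0.31 for small heat shock proteins and -0.29 for HSP70, HSP90, HSP100 and co-chaperones (0.04 after quantile normalization). The limit of high signals named for OE applies here too. Jasmonate genes shifted up with 1 of 2 past the threshold, also when adjusted over the list alone, and flavonoid genes with 0 of 5, and 1 over the list alone (each adjusted p = 0.0476; adjusted p = 0.39 and 0.462 with an estimated correlation, 0.0947 and 0.0865 after quantile normalization, and 0.313 and 0.455 without WT heat 1). The count was 106 without WT heat 1, 454 without WT heat 2, 13 without RD heat 1 and 16 without RD heat 2, 521 with the array series as a block, 337 within its first series and 606 with the replicate number as a block within control and NaCl, and 2296 probe sets had an unadjusted p under 0.05.

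Under NaCl, small heat shock proteins were lower in RD than in WT. HSP23.6-MITO stood at 469.6 ± 462 against 4476 ± 341 (-3.73 ± 0.65, 13.2-fold, adjusted p = 0.021) and HSP17.6II at 510.2 ± 273 against 3817 ± 518 (-3.01 ± 0.51, 8.04-fold, adjusted p = 0.0185). Of the fixed list, 2 of 5 fell and 5 when adjusted over the list alone, with a median of -3.01 (adjusted p = 3.38e-10, but adjusted p = 0.0908 with an estimated correlation). By locus alone, 5 of 14 were lower, including AT1G52560 (-4.84), AT5G37670 (-2.69) and AT5G51440 (-1.46), with a median of -2.18 (adjusted p = 1.01e-21, and adjusted p = 0.0183 with an estimated correlation). AT5G48570 alone was lower among 13 HSP70, HSP90, HSP100 and co-chaperone genes, at 3561 ± 51.4 against 13700 ± 3390 (-1.92 ± 0.25, adjusted p = 0.00364). With 6 of these when adjusted over the list alone, their median was -0.83 (adjusted p = 1.46e-09, but adjusted p = 0.0908 with an estimated correlation). The highest adjusted p without single arrays was 0.112 for HSP23.6-MITO (WT NaCl 1, WT NaCl 2 or RD NaCl 2), 0.136 for HSP17.6II and 0.0673 for AT5G37670 (each WT NaCl 2 or RD NaCl 2), 0.147 for AT1G52560 (WT NaCl 1, WT NaCl 2 or RD NaCl 2) and 0.167 for AT5G51440 (RD NaCl 1, WT NaCl 2 or RD NaCl 2). The called small heat shock proteins numbered 0 of 14 without WT NaCl 2 or RD NaCl 2 and 4 without WT NaCl 1 or RD NaCl 1.

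**Figure D4:**
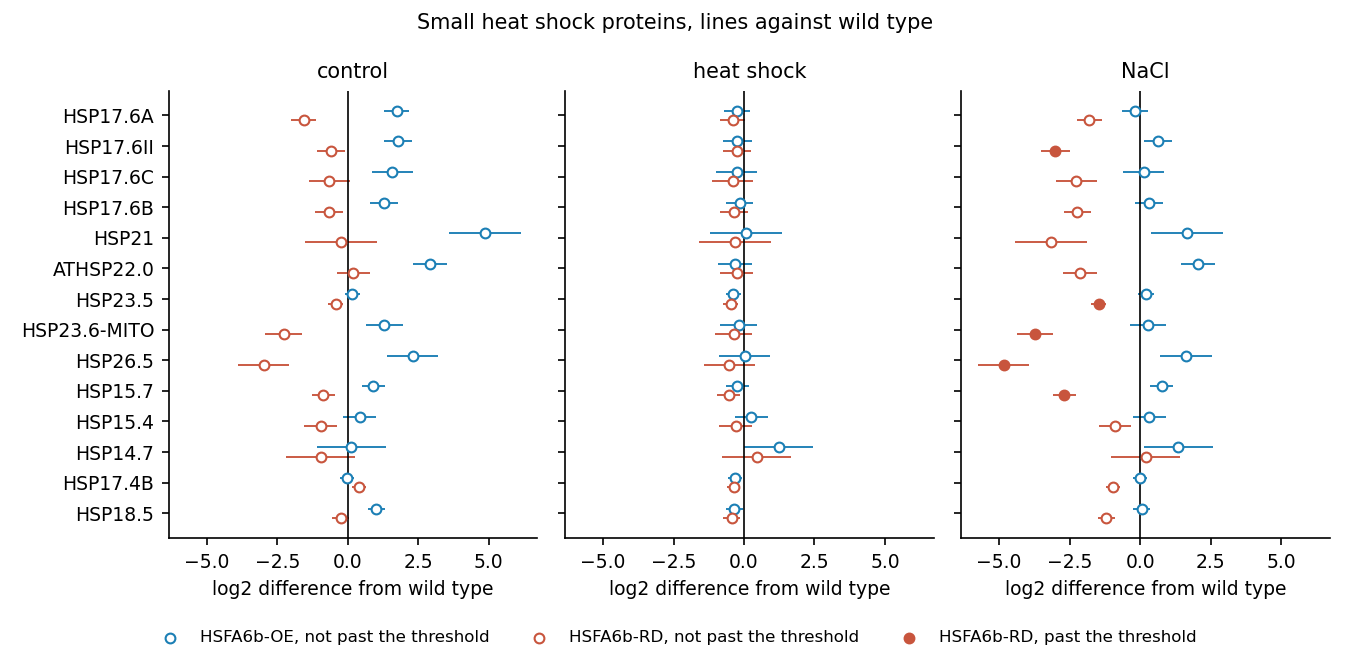
Points are log2 differences of OE and RD from wild type for 14 small heat shock proteins in each treatment, bars are standard errors, and filled points passed the threshold. The 5 filled points all belong to RD under NaCl, between -4.84 and -1.46.

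Other genes separated RD from WT under NaCl, where 76 probe sets passed, 5 higher and 71 lower. IQD19 (-3.57 ± 0.30, at least 6.51-fold, adjusted p = 0.000235) stood at 5.6 ± 0.849 against 66.25 ± 0.495, and LCR68 was lower (11.2-fold, adjusted p = 0.0034). The temperature-induced lipocalin TIL was also lower (-1.42 ± 0.21, 2.67-fold, adjusted p = 0.00942), with adjusted p = 0.0691 without WT NaCl 2 or RD NaCl 2. BZIP34 (-2.82 ± 0.40) and the sugar transporter SWEET14 (-2.79 ± 0.44) passed, but were not called Present in either group, and SWEET14 had adjusted p = 0.0857 without WT NaCl 1 or RD NaCl 2. IAA1 alone was lower among 7 auxin response genes, 2 when adjusted over the list alone, at 136.5 ± 18 against 446 ± 140 (-1.68 ± 0.32, adjusted p = 0.0331). It reached 0.172 without RD NaCl 1, WT NaCl 2 or RD NaCl 2, and 0.094 after quantile normalization. The auxin list shifted down (median -0.95, adjusted p = 0.00176, but adjusted p = 0.385 with an estimated correlation and 0.579 without WT NaCl 2). The genes responsive to ABA and osmotic stress (median 0.41) and the jasmonate genes (median 0.70) shifted up with no member past the threshold, each with adjusted p = 0.0453, adjusted p = 0.103 after quantile normalization, and adjusted p = 0.528 and 0.385 with an estimated correlation. Without single arrays these reached 0.561 (WT NaCl 1, where the direction turned, or RD NaCl 2) and 0.387 (any of the 4). The count was 39 without WT NaCl 2 186 within the first array series and 169 with the replicate number as a block within control and NaCl, 1063 probe sets had an unadjusted p under 0.05, and on RD NaCl 1 the mitochondrial transcripts stood apart (median 8.32), without which 88 passed.

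The differences of responses asked whether a line's response to a treatment departed from that of WT. The loss of IQD19 with NaCl was larger in RD, from 157.1 ± 4.53 to 5.6 ± 0.849, by a log2 difference of -3.62 ± 0.43 (adjusted p = 0.0139). It did not pass without WT control 1, RD control 1, RD control 2 or WT NaCl 2, with a highest adjusted p of 0.122, and had adjusted p = 0.279 (-2.75) with signals raised to the lowest one called Present. In this comparison 3 probe sets passed, all lower, 0 without WT control 1, RD control 1, RD control 2 or WT NaCl 2, and 5 without RD NaCl 2, with 6 for the array series as a block, 20 within its first series and 9 with the replicate number as a block within control and NaCl. Small heat shock proteins had 0 past the threshold, 2 when adjusted over the list alone, and a median of -2.33 (adjusted p = 0.000425, but adjusted p = 0.449 with an estimated correlation and at most 0.13 without WT control 1, RD control 2 or RD NaCl 2). Auxin response genes were lower (median -1.09, adjusted p = 0.000425) and genes responsive to ABA and osmotic stress higher (median 0.66, adjusted p = 0.000881), with adjusted p = 0.449 and 0.462 with an estimated correlation, 0.35 for auxin without WT NaCl 2, and at most 0.755 for the other without WT NaCl 1, where its direction turned, RD control 2 or RD NaCl 2. For NaCl, 499 probe sets had an unadjusted p under 0.05 in RD, fewer than the share of 0.05 expected where nothing differs.

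The log2 difference between heat shock and control of small heat shock proteins was lower in OE than in WT by a median of -2.02. OE minus WT was 1.78 under control and -0.24 under heat shock. Past the threshold were 0, and 4 of 5 when adjusted over the list alone (camera adjusted p = 7.57e-06, but adjusted p = 0.315 with an estimated correlation). On the heat shock arrays HSP17.6A lay between 25761 and 41186 and HSP21 between 20595 and 30608. Whether signals this high can still show a difference was not tested. Jasmonate genes (median 1.70, 2 when adjusted over the list alone) and auxin response genes (median -1.09, 2 when adjusted over the list alone) also differed for OE, with adjusted p = 0.00312 and 0.00176, adjusted p = 0.315 and 0.423 with an estimated correlation, and 0.145 for each without WT heat 1. Over all probe sets 2 passed, both lower, or 4 with 50% higher after quantile normalization, and 1070 had an unadjusted p under 0.05. Left-out arrays gave 6 (WT heat 1), 102 (WT heat 2), 1 (OE heat 2) and 0 (each of WT control 1, WT control 2, OE control 1, OE control 2 and OE heat 1), and the replicate block within control and NaCl 9. For NaCl in OE 0 probe sets passed with limma, 191 had an unadjusted p under 0.05, and the small heat shock protein list had a median of -1.15 (1 when adjusted over the list alone; adjusted p = 7e-06, but adjusted p = 0.622 with an estimated correlation and 0.149 without WT control 1). The heat shock response of RD gave 1 probe set, lower, or 2 with 50% higher after quantile normalization, and 1106 at an unadjusted p under 0.05. Left-out arrays gave 0 (RD control 1), 7 (WT heat 1), 128 (WT heat 2), 3 (WT control 2) and 2 (each of RD heat 1 and RD heat 2), and that block 2. Its small heat shock proteins had a median of 0.35 (adjusted p = 0.38).

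OE and RD carry an overexpressed and a dominant-negative form, and their differences from WT were set against each other across genes, which are not independent replicates. The correlation was 0.228 under control, 0.611 under heat shock and 0.218 under NaCl, with 54.9%, 73.8% and 54.7% of probe sets on the same side of 0. Because both use the same WT arrays, unchanged groups gave mean correlations of 0.465 (range 0.329 to 0.728), 0.736 (0.687 to 0.771) and 0.582 (0.415 to 0.813). The observed correlation lay below its range in every treatment. The covariances were 0.035, 0.258 and 0.045. For unchanged groups they were 0.074 (range 0.043 to 0.153), 0.204 (0.181 to 0.215) and 0.204 (0.09 to 0.405), or 0.043, 0.211 and 0.09 with replicate numbers matched. The observed covariance lay above this range under heat shock, by 0.054 over the mean. Under control and NaCl the observed covariance, 0.035 and 0.045, lay below the range. The replicate numbers were taken to pair arrays in these 2 treatments. The like values there are therefore those with numbers matched, 0.043 and 0.09, the lowest of each range. Each range comes from 4 ways of setting the signs of the groups' own replicate differences, so it does not measure a sampling spread. JMT, TRM24 and the probe set described as a putative heat shock protein were among 5 probe sets higher in both lines under heat shock. With single arrays left out, the correlation under control was 0.47 (WT control 1) and 0.476 (WT control 2), but 0.162 without OE control 2. That under NaCl was 0.57 (WT NaCl 1) and 0.631 (WT NaCl 2), but 0.056 without OE NaCl 2.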

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

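The tests of a difference between responses were planned, whereas AT2G32140 and the probe sets described as heat shock protein 18 and SAUR-AC1 were chosen, and the rerun with raised signals was added, after their values were seen.

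In 6 cases a line's response to a treatment differed from that of wild type in the test of that difference. AT2G32140, described as a putative disease resistance protein, had a lower log2 response to heat shock in OE (-4.47, SE 0.621, adjusted p = 0.0438) and in RD (-5.73, adjusted p = 0.00501), and to NaCl in RD (-4.28, adjusted p = 0.0475). Its signal in the WT controls was 1.05 ± 0.0707 with no Present call, near background, against 17 ± 3.82 in the OE and 17.35 ± 3.18 in the RD controls. The signal reached 415.3 in OE heat, 178.5 ± 23.3 in RD heat and 133.6 ± 57.6 in RD NaCl. For OE under heat shock, AT2G32140 missed the threshold without any 1 of WT control 1, WT control 2, OE control 1, OE control 2, OE heat 1 and OE heat 2 (highest adjusted p 0.278). For RD under heat shock it did so without RD control 1 (0.057), and for RD under NaCl without any 1 of the 6 arrays of WT control, RD control and WT NaCl or without RD NaCl 2 (highest 0.186). With every signal raised to the lowest one called Present on its array, the 3 differences of AT2G32140 were -1.55, -2.81 and -1.36 (adjusted p = 0.776, 0.559 and 1), so a smaller response is not shown for it.

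The probe set described as heat shock protein 18 had a lower log2 response to heat shock in OE, from 1033 to 32910 ± 296, than in WT, from a lower control level of 146.2 to 37880 ± 805 (-3.03, SE 0.364, adjusted p = 0.0174). Whether this probe set can still show a difference at such high signals was not tested. Without any 1 of WT control 1, WT control 2, OE control 1, OE control 2, OE heat 1 and OE heat 2 it did not pass, with a highest adjusted p of 0.212. The probe set described as SAUR-AC1 went from 334.5 ± 33.1 to 44.45 with NaCl in RD and stood at 541.4 ± 7.21 in WT NaCl (-3.49, SE 0.503, adjusted p = 0.0475). It did not pass without any 1 of the 6 arrays of WT control, RD control and WT NaCl or without RD NaCl 1 (highest 0.205). With raised signals its difference was the same and its adjusted p = 0.126. IQD19 fell more with NaCl in RD than in WT (-3.62, SE 0.43, adjusted p = 0.0139), and reached 0.122 at most without WT control 1, RD control 1, RD control 2 or WT NaCl 2, and -2.75 (adjusted p = 0.279) with raised signals, whereas heat shock protein 18 had adjusted p = 0.0153.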

How the results depend on the processing

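In this part, the lists from descriptions, the interest in the doubted RD arrays and the replicate block within control and NaCl were chosen after the data were seen. Beyond the smaller number of arrays left by each left-out setting the cause of a moved count was not tested. Dim probe sets limit these results, since signals under the lowest Present signal of an array (6.2 to 14.6) stand near background. Of 857 gene results none reversed under the alternatives or with an array left out (0 of 3440), and fewer passed with quantile normalization (38 lost), no detection filter (20), log2 of the signal plus 32 (11), the replicate block (1), the array series block (8), without the 3 arrays of the second series (26), without the intensity trend (20), in a fit of only the groups compared (107) and with single arrays left out (539 of 3440). The series value table changed none (0). A reversal was largely excluded in advance, since all 857 results had passed the threshold. The series value table, the replicate block and the fits without filter, without trend or of only the groups compared leave every log2 difference unchanged. Outside the differences of responses, the rule's largest rises and falls also had arrays that did not overlap between groups. Leaving out an array cannot turn the direction of these. The check of labels by the HSFA6B level was not run, since no probe set carries that name.

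Heat shock calls were 5220 in WT with the array series block and 1593 with only the groups compared, 4921 in OE without the 3 arrays and 5497 with only the groups compared, and 4232 in RD without the 3 arrays. NaCl calls in WT were 2122 with only the groups compared. With the replicate number as a block, OE under heat shock had 75 calls and RD 88; the replicate differences of 36 pairs of groups correlated at -0.076 to 0.627 (median 0.06, 11 over 0.1), so the numbers were not taken to pair arrays across treatments. With the replicate block within control and NaCl, calls numbered 432 for OE and 606 for RD under heat shock, 1 for OE and 169 for RD under NaCl and 32 for RD under control, and the differences of responses had 9 in OE and 2 in RD for heat shock and 9 in RD for NaCl. That block ended no call of a named gene (0 of 45) or fixed list. Besides small heat shock proteins in OE under NaCl, 5 more tests of fixed lists passed with it: ABA and osmotic stress in RD under control (0.0197), antioxidant and zinc finger genes in RD under heat shock (0.0244) and its difference of responses (0.0311), and, for the NaCl differences, auxin in OE (0.0155) and jasmonate in RD (0.0459), with adjusted p = 0.53, 0.332, 0.366, 0.905 and 0.351 with an estimated correlation. With the array series block OE under heat shock had 112 calls, RD under control 15 and RD under heat shock 521. Without the 3 arrays, OE had 119 under heat shock and 6 under NaCl, and RD 26 under control, 337 under heat shock and 186 under NaCl. With only the groups compared, OE under heat shock had 0 with limma (1899 at an unadjusted p under 0.05), and RD 3 under control, 1 under heat shock and 0 with limma under NaCl (477 unadjusted). RD under control had 13 with quantile normalization and 5 with log2 of the signal plus 32, under which OE under NaCl had 1.

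The difference of the heat shock response had 4 calls in OE with quantile normalization and without the trend, 1 with no filter, the replicate block or only the groups compared, 5 with the array series block and 8 without the 3 arrays. In RD it had 2 with quantile normalization, log2 of the signal plus 32, the replicate block or no trend, 12 without the 3 arrays and 0 with only the groups compared in limma (1185 unadjusted). For NaCl, the difference in OE had 1 without the 3 arrays. In RD it had 1 with quantile normalization, the replicate block or no trend, 0 in limma with no filter (803 unadjusted), log2 of the signal plus 32 (500) or only the groups compared (384), 6 with the array series block and 20 without the 3 arrays. Of 256 list tests 68 passed, 18 of them with an estimated correlation, and 120 of 320 for the added lists, those from descriptions and of the 2 organelle genomes. The correlation of OE and RD effects was 0.44 under control, 0.552 under heat shock and 0.405 under NaCl with no filter, and 0.69 under heat shock and 0.421 under NaCl without the 3 arrays. Without these, 1547 probe sets were lowered by both treatments.

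With single arrays left out, heat shock calls ran from 1682 (WT control 2) to 3388 in WT, 1402 (OE control 1) to 1932 in OE and 1074 (RD heat 1) to 1444 in RD. NaCl calls ran from 2537 (WT NaCl 2) to 6017 in WT, 2076 (OE NaCl 2) to 4161 in OE and 3134 (RD control 2) to 4296 in RD. OE against WT gave 2 to 6 under control, 1 (OE heat 1) to 662 (WT heat 2) under heat shock and 0 to 14 (WT NaCl 1) under NaCl. RD against WT gave 6 to 10 under control, the highest without the doubted RD control 2, 13 (RD heat 1) to 454 (WT heat 2) under heat shock and 39 (WT NaCl 2) to 94 under NaCl. The differences of responses gave 0 to 102 (WT heat 2) for heat shock and 0 to 0 for NaCl in OE, and 0 to 128 (WT heat 2) and 0 to 5 in RD. List calls ran from 59 to 74. Correlations ran from 0.162 to 0.476 under control, 0.527 to 0.775 under heat shock and 0.056 (OE NaCl 2) to 0.631 under NaCl. Both treatments raised 342 to 542 and lowered 269 to 1169 probe sets.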

Other observations

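The lists drawn from descriptions were chosen after the data were seen, the auxin one after fold changes were known, and so were the tests on like plastid probe sets, on 3' to 5' ratios, on shared calls under other treatments and on the size of shared differences.

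Lists drawn from the descriptions in the array files show further groups that moved with NaCl in wild type. Ribosomal proteins of the 40S and 60S subunits shifted down, with 85 of 113 lower and 1 higher (adjusted p = 3.89e-15, and adjusted p = 0.261 with an estimated correlation). Cell wall groups did too, with 22 of 37 xyloglucan enzymes and expansins lower (median -2.04, adjusted p = 2.42e-05 and 0.0402) and 15 of 28 extensins and arabinogalactan proteins (median -1.60, adjusted p = 0.000109 and 0.0484), each second value with an estimated correlation, as below. Peroxidases (34 of 73 lower, median -1.22, adjusted p = 3.26e-05 and 0.123), histones (21 of 34 lower, median -1.10, adjusted p = 2.99e-05 and 0.213) and photosystem and chlorophyll-binding proteins (6 of 42 lower, median -0.48, adjusted p = 0.0392 and 0.8; 0.543 at most without WT control 1 or WT NaCl 2) shifted down. Lists of transcription factors shifted up, with 25 of 56 AP2 factors (median 1.14, adjusted p = 8.24e-08 and 0.00409), 11 of 27 WRKY factors (median 0.84, adjusted p = 6.29e-05 and 0.0484) and 6 of 33 NAC factors higher (median 0.24, adjusted p = 0.0324 and 0.333; 0.181 at most without WT control 1 or WT NaCl 2). Protein phosphatases 2C (13 of 36 higher, adjusted p = 0.00129 and 0.0484) and glutathione transferases (13 of 38 higher, adjusted p = 0.012 and 0.261) also shifted up. So did the described heat shock factors (13 of 24 higher, adjusted p = 4.37e-07 and 0.00409), HSP70, HSP90, HSP100 and DnaJ proteins (18 of 65 higher, adjusted p = 4.03e-05 and 0.00409) and small heat shock proteins (11 of 19 higher, adjusted p = 6.52e-09 and 0.0484). Late embryo proteins and dehydrins (28 tested, adjusted p = 0.489), aquaporins (20 tested, adjusted p = 0.198), cytochromes P450 (132 tested, adjusted p = 0.763) and auxin-related genes (67 tested, adjusted p = 0.556) did not pass.

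With heat shock in wild type, histones (17 of 34 lower, adjusted p = 0.00129 and 0.407) and auxin-related genes (22 of 67 lower, adjusted p = 0.00399 and 0.267) shifted down. Late embryo proteins (4 of 28 higher, adjusted p = 0.000886 and 0.267) and AP2 factors (12 of 56 higher, adjusted p = 0.00129 and 0.0464) shifted up, as did the described small heat shock proteins (12 of 19 higher, adjusted p = 3.09e-21 and 0.0086) and HSP70, HSP90, HSP100 and DnaJ proteins (24 of 65 higher, 3 lower, adjusted p = 1.67e-12 and 0.000212). Between genotypes, the 113 ribosomal proteins shifted up in RD against WT under heat shock (median 0.79, 0 past the threshold, adjusted p = 1.61e-35 and 0.555), in OE against WT under heat shock (median 0.51, adjusted p = 4.67e-15 and 0.608) and in RD under NaCl (median 0.32, adjusted p = 3.72e-15 and 0.328). The 28 late embryo proteins shifted down in RD under control (median -0.96, adjusted p = 1.82e-11 and 0.102). Under NaCl, 14 of 67 auxin-related genes were lower in RD (median -0.45, adjusted p = 7.62e-11 and 0.0183), among them the probe set described as SAUR-AC1 (44.45 against 541.4, adjusted p = 0.000654). The auxin-related calls numbered 10 without WT NaCl 1, 6 without RD NaCl 1 or RD NaCl 2 and 4 without WT NaCl 2. In the same line, plastid transcripts shifted up with NaCl against control (11 of 69 higher, median 0.92, adjusted p = 5.18e-07 and 0.306; 0.0715 without RD control 2).

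Heat shock raised transcripts of the mitochondrial genome list in all 3 genotypes. Scaling of the arrays is argued against by the medians after quantile normalization, 3.578, 3.6 and 3.322 in WT, OE and RD. DNA carry-over or less selective copying is argued against by 28 plastid probe sets of like signal, with medians of -0.062, -0.134 and 0.45. RNA degradation of whole samples is argued against by the 3' to 5' log2 ratio of actin and GAPDH control probe sets. Its mean was 0.266 higher on heat shock arrays, with OE heat 1 at 1.62 and the control arrays at 0.3 to 0.99. These 2 transcripts cannot show decay or processing of the mitochondrial RNAs themselves, which stays open. The heat treatment itself, a larger polyadenylated share of these RNAs and reading of nuclear copies were not tested and stay open.

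Small heat shock proteins were lower in RD than in WT under NaCl, with a median of -2.18 over 14 members, and 5 calls that became 0 without WT NaCl 2 or RD NaCl 2. A single RD array is argued against by medians of -2.766 and -1.414 without RD NaCl 1 and RD NaCl 2, and a single WT array, 1 of them from the second series, by -2.088 and -2.085. A weaker NaCl response of all genes is argued against by 302 other probe sets raised by NaCl, with a median of 0.055 (quartiles -0.362 and 0.367). Against OE, 14 of 14 members were also lower in RD (median -2.469, 7 past the threshold), which rests on the same RD NaCl arrays. Of all 132 probe sets called between RD and OE under NaCl, 130 were lower in RD, so this direction is not particular to small heat shock proteins. No biological explanation was tested, and the form of HSFA6b that RD carries stays open.

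Under heat shock 5 probe sets were higher in both lines, where independent lists would share 0.02, and 0 of them passed in a difference of responses. Without WT heat 1, of the second series, 2 of the 5 passed in both comparisons, and 5 without WT heat 2, but the differences ran from 2.76 to 7.14 with WT heat 1 and from 2.76 to 7.70 without it, while the highest SE went from 0.63 to 0.74. When dim signals are raised, the smallest difference was 1.16 with WT heat 1 and 1.21 (SE 0.59) without it. The lowest and highest differences thus did not shrink without that array. Since 4 of the 5 were not called Present in WT heat and only 1 WT heat array is then left, an effect of WT heat 1 stays open. Chance values of the shared WT heat shock arrays cannot be told apart from a change common to both lines, because 1 of the 5 also passed under control or NaCl, where other WT arrays serve. That 1 is the probe set described as a putative heat shock protein (5.95 and 7.24 in the OE and RD controls), and if it measures HSFA6B, which is not given in the sources used here, its calls say nothing of a further change common to both lines.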
